A study of Danio rerio with 4 samples.

How the data were processed

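Gene expression was measured by droplet single-cell RNA sequencing of dissociated telencephalon cells of adult zebrafish, sorted by FACS with the viability dyes Sytox Blue and a Dycle Ruby dye. The 4 libraries, 1 per group, were wild type with PBS, wild type with Ab42, and the line with the genotype field abca7 +/-, titled abca7 k/o, with PBS and with Ab42. The deposited values are raw UMI counts per gene and barcode that the authors obtained with Cell Ranger 6.1.2 against the genome build GRCz11 with annotation release 105. STAR and Seurat are also named in the submitters' processing notes. The smallest barcode had 500 UMIs in the files. No other normalisation had been applied to the counts.

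The matrices listed 32520 features under 31819 symbols. Of these, 865 were listed by Ensembl ID only, and 498 of them, abca7 among them, were named from a table of gene identifiers. Features that shared a symbol, 533 symbols in all, were summed. Barcodes with at least 200 genes and at most 10% mitochondrial UMIs were kept, which removed 197, 143, 111 and 341 barcodes in the order above.

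Doublets were scored per library with Scrublet in scanpy, at an expected rate of 0.8% per 1000 barcodes. It marked 0.0198%, 23.2%, 0.0619% and 0.664% of the barcodes, against expected rates of 4.03%, 18.0%, 10.3% and 11.2%. The 5219 barcodes marked in the wild-type Ab42 library had a median of 1145 UMIs, less than the 1521 of the others, which doublets would not have. The marked barcodes were therefore kept, in all libraries. That reason did not hold in the libraries labelled abca7 +/-, where the 8 and 93 marked barcodes had medians of 2520.5 and 4335 UMIs against 1714 and 2320. Keeping the marked barcodes departed from the choice made before the data were examined, which was to remove them, and removal was run as an alternative.

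Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen with the library as batch, clipped at 10 standard deviations. A graph of 15 neighbours on 30 principal components was clustered by the Leiden method at resolution 1, without integration of the libraries. A cluster was named when 1 of 19 fixed marker lists had both the highest mean ratio and the most members among the 10 genes with the highest ratio in that cluster (found in at least 20% of its cells), and at least 3 of its markers were found in at least 10% of the cells. This named 18 of the 32 clusters. Shares of cells have exact binomial (Clopper-Pearson) 95% intervals.

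Within the neuron, radial glia / astroglia, microglia and oligodendrocyte classes, UMIs were summed per library and expressed as counts-per-million of the UMIs of the class. Each class had at least 100 cells in every library. The 4 comparisons were Ab42 over PBS in both lines and the line labelled abca7 +/- over wild type after both injections. With 1 library per group no test was made. Log2 ratios had 1 CPM added to both sides and exact conditional (Clopper-Pearson) 95% intervals of the counts, and levels had exact Poisson intervals. A count of 0 was read as allowing up to 3 counts. Shares of cells with a UMI of a gene were taken after each cell was thinned to 1000 UMIs, with shallower cells left out, and again without thinning.

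The 23 gene lists were fixed before the data were examined, as were the comparisons, the marker lists and the rule for named genes. For each list, class and comparison the median log2 ratio of the members with at least 20 UMIs was placed among 10000 random lists of the same size, matched on mean level in 20 bins, and members differing at least 1.5-fold were counted. Some list members were not among the symbols of the matrices, such as dcx, cd68 and ighm. Correlations across genes used genes with at least 50 UMIs.

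Named genes were abca7, the members of the NPY and neurotrophin lists, and the 3 highest and 3 lowest genes of each class and comparison. These were ranked by the interval bound nearest to no difference, among genes with at least 50 UMIs and with UMIs in at least 2% of the cells. Mitochondrial, ribosomal protein and haemoglobin genes, markers of other classes and genes without a symbol were left out of that ranking. For lists, the members with the largest ratios were named, along with members such as apoeb, sox11a and hsp70.1 chosen after their values were seen. Of the 96 places in the ranking, 79 went to genes that also differed more than 2-fold in the same direction outside the class, so a ranking without genes differing more than 1.5-fold in the same direction outside the class was added after the data were seen.

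The ratios were tested on simulated data, with Poisson counts drawn from the pooled neuron profile of each comparison at its depths and 200 genes doubled or halved. For the 4 comparisons in turn, the interval excluded equality on the right side for 98%, 100%, 100% and 97% of the doubled genes and for 89%, 93%, 91% and 90.0% of the halved ones. The intervals held the true ratio for 95.7%, 95.6%, 95.7% and 96.1% of genes. The counts were drawn with the same counting error that the intervals assume, so this coverage followed from the simulation. The simulated counts had no spread between cells or between libraries. Coverage and detection in the real counts, where single cells can hold a large part of the UMIs of a gene, were therefore not tested. A list of 20 doubled genes reached percentile 100 in each comparison.

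Alternatives covered the barcode filter, the doublets, the Leiden resolution, centring of genes within libraries, TMM scaling, scaling without mitochondrial, ribosomal and haemoglobin genes, the pseudocount, the mean over cells, the UMI minimum of list members, the thinning depth and the UMI minimum of correlations. Further ones were added after the data were seen: subtraction of background npy, leaving out the neurons richest in npy, leaving out list members or ranked genes that also differed outside the class, shares of all kept cells and a minimum of 10 npy UMIs. Reads, splicing and the mutation itself were not analysed here, and unnamed clusters were left out of the comparisons within classes. Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, python-igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.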

Results

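Cells of the adult zebrafish telencephalon were profiled by droplet single-cell RNA sequencing in 4 libraries, 1 per group: wild-type fish injected with PBS, wild-type fish injected with amyloid-beta peptide (Ab42), and fish of the line labelled abca7 +/- injected with PBS or with Ab42. The libraries held 5040, 22515, 12921 and 14006 barcodes in that order, of which 4843, 22372, 12810 and 13665 were kept. The kept cells had a median of 2182, 1360, 1732 and 2397 unique molecular identifiers (UMIs), and the share of cells with fewer than 1000 UMIs was highest in the wild-type Ab42 library at 38.2%. There were no replicate libraries, so every interval given with a value is a 95% interval that covers counting error only, and no difference was tested against the spread between animals. Levels are given as CPM, the counts-per-million of the UMIs of the cells in question. Ratios are log2 values with 1 CPM added to both sides, and their intervals were taken from the counts without that addition.

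The targeted gene, abca7, encodes a lipid transporter and was examined first. Over all kept cells its level was 5.36 CPM (4.34 to 6.53) in the wild-type PBS library and 5.30 CPM (4.72 to 5.93) in the wild-type Ab42 library. It was 7.85 CPM (6.97 to 8.81) in the PBS library labelled abca7 +/- and 9.84 CPM (8.93 to 10.8) in the Ab42 library labelled abca7 +/-. These levels rested on 97, 303, 287 and 430 UMIs of 18109509, 57194875, 36559278 and 43699880 UMIs in kept cells. In neurons the levels were 5.99, 3.93, 6.68 and 6.36 CPM, and in radial glia 2.17, 9.19, 8.89 and 17.4 CPM, the first of these from 4 UMIs. The abca7 level was thus not lower in either library labelled abca7 +/- than in the wild-type library with the same injection. The titles of both samples read abca7 k/o, while their genotype field reads abca7 +/-. The kind and place of the mutation are not given in the sources used here, and counts of transcript ends cannot tell a mutated transcript from an intact one.

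Neurons, glia, immune cells and vascular cells were found in all 4 libraries. The clusters named as neurons held 987, 1584, 2346 and 1371 cells, comprising 1 glutamatergic-like cluster (cluster 4) and the GABAergic-like clusters 8 and 15. Radial glia / astroglia-like cells formed cluster 3, with the markers slc4a4a and cx43 among its leading genes. Microglia-like cells formed clusters 13 and 17, and oligodendrocyte-like cells formed cluster 20. The names were rebuilt from fixed marker lists, and 18 of the 32 clusters received one. The cells left unnamed made up 35.9% and 74.2% of the wild-type PBS and Ab42 libraries and 44.99% and 56.1% of the libraries labelled abca7 +/-. The largest unnamed cluster, cluster 0, took 97.9% of its cells from the wild-type Ab42 library and may stand for that library rather than for a cell type. The unnamed clusters 0, 1, 2, 7 and 22 also scored best for neuron markers, with 29 to 32 of them detected but none among the 10 leading genes of the cluster, so the neuron counts hold only the clusters that met the naming rule. No cluster met that rule for B cells, fibroblasts, ependymal cells or epithelial cells, although cluster 26 scored best for fibroblast markers and clusters 5 and 28 for ependymal markers. The leading genes of cluster 5 included the radial glia marker gfap, along with foxj1a, mcm4, ccnd1 and ldlra. It held 3.70%, 3.37%, 6.14% and 5.99% of the kept cells in library order and was left out of the radial glia values.

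Neuroblast-like cells, which express genes such as sox11a and insm1a while neurons mature, made up 2.74% (2.19 to 3.38) and 1.90% (1.57 to 2.29) of the named cells in the wild-type PBS and Ab42 libraries. They made up 9.76% (9.08 to 10.5) and 7.92% (7.25 to 8.63) in the libraries labelled abca7 +/-. The unnamed cluster 23 also scored best for neuroblast markers, with 11 detected, and is not part of these shares. Its leading genes included dlx2a, dlx1a, insm1a and insm1b, and it held 0.351%, 0.340%, 1.78% and 1.94% of the kept cells in library order. Endothelial-like cells had a lower share of the named cells in both libraries labelled abca7 +/-, at 2.71% and 1.88%, than in the wild-type libraries, at 9.12% and 8.30%. T or NK-like cells made up 13.9% of the named cells in the Ab42 library labelled abca7 +/- and 5.77%, 4.31% and 6.27% in the other libraries. Radial glia-like cells made up 20.1% in the wild-type Ab42 library and 13.3%, 12.9% and 11.8% elsewhere, but of all kept cells they made up 8.51%, 5.19%, 7.10% and 5.19% in library order, so a higher share there depended on leaving out the unnamed cells. The cells had been dissociated and sorted by FACS with viability dyes, so shares also carry the yield of both steps.

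**Figure D1:**
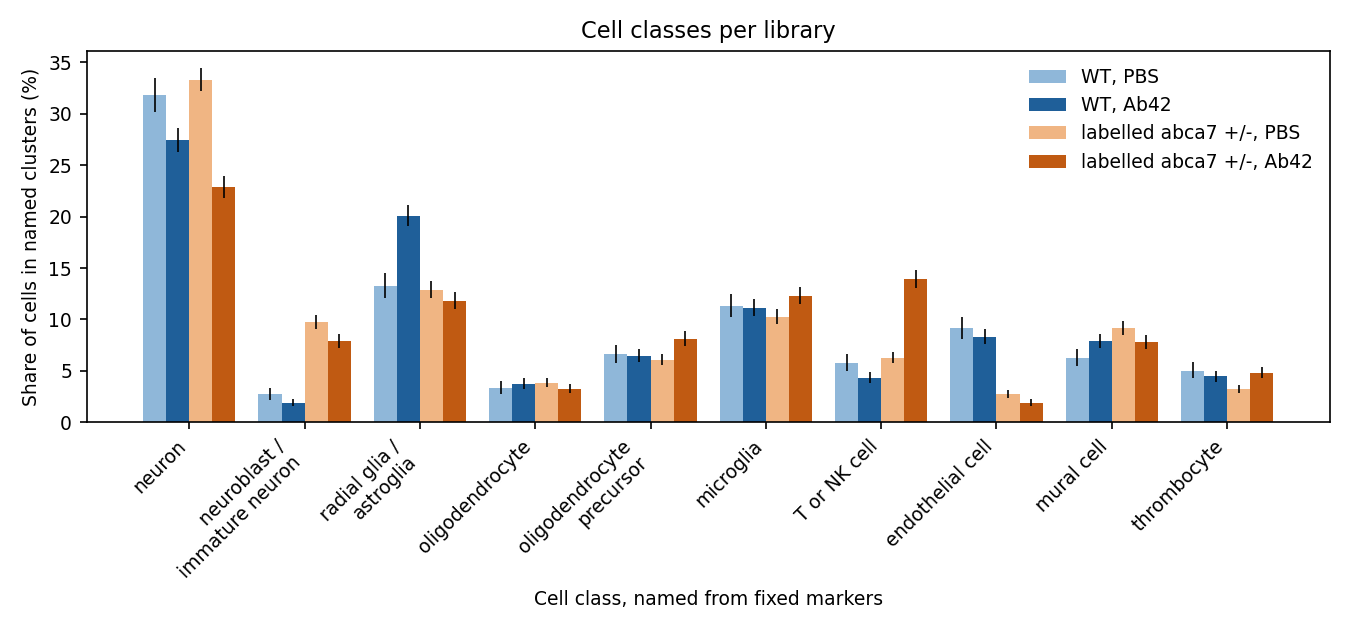
Bars give the share of cells in named clusters (percent, y axis) in each cell class (x axis) for the 4 libraries, and lines are exact binomial 95% intervals. Neuroblast-like cells reached 9.76% and 7.92% in the libraries labelled abca7 +/- against 2.74% and 1.90% in the wild-type libraries.

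The first comparison set Ab42 against PBS in wild-type fish. The level of npy, which encodes neuropeptide Y, was about equal in neurons of both libraries, at 1130 CPM after Ab42 and 1109 CPM after PBS (log2 ratio 0.03, interval −0.02 to 0.07). This depended on the setting, as the ratio was −1.36 with genes centred within each library, −0.57 without the richest 1% of neurons, 0.19 at Leiden resolution 0.5, 0.20 with doublets removed and 0.10 with TMM factors. The neuron level covered opposite differences in the GABAergic-like clusters, with log2 ratios of npy of −2.21 in cluster 8 and 2.57 in cluster 15, and cluster 15 made up 5.29% of the kept cells after PBS and 0.974% after Ab42. In cluster 15 the level was 12001 against 2018 CPM, and 6332 against 1542 CPM without the richest cell of each library, which held 3803 of the 7620 npy UMIs after Ab42. Glutamatergic-like neurons had a ratio of 2.31 but 0 cells with at least 10 npy UMIs, and their mean of 0.986 against 0.246 UMIs per cell was near the 0.959 and 0.256 of microglia-like cells below 10 npy UMIs, so that ratio is read as background. Within the neuron class the npy UMIs came mostly from GABAergic-like neurons, at 2694 and 2818 CPM. The related peptide gene pyyb was higher after Ab42 in neurons, at 376 against 22.1 CPM (log2 ratio 4.03), although 1 cell held 58.0% of the 3445 UMIs. The gene pyya was at 686 and 503 CPM (0.44), from log2 ratios of 1.65 in glutamatergic-like and −1.08 in GABAergic-like neurons. It was also higher in oligodendrocyte-like (2.85), radial glia-like (1.33) and microglia-like cells (0.78), so the 1.65 was not separated from background. The receptor gene npy1r was lower, at 3.82 against 7.36 CPM (−0.79). The share of neurons with an npy UMI, at 1000 UMIs per cell, was 22.5% (20.4 to 24.6) after Ab42 and 12.3% (10.3 to 14.6) after PBS. In microglia-like cells, which should not express npy, that share was 25.2% and 4.71%, so the neuron share after Ab42 did not exceed background. The shares were taken from 1574 and 933 neurons, leaving out 10 and 54 shallower cells, with median depths of 4838 and 4483 UMIs in neurons and 4427 and 6857 UMIs in microglia-like cells, of which 123 and 76 were left out. Without thinning the neuron shares were 60.04% and 23.3%, and those of microglia-like cells 57.9% and 21.6%.

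The npy level of neurons rested on few cells in every library. The single richest neuron held 13.1% of the npy UMIs of the wild-type PBS library, 36.8% after Ab42, and 14.1% and 26.1% in the PBS and Ab42 libraries labelled abca7 +/-. With the 1% of neurons richest in npy left out, the levels were 397 and 266 CPM in the wild-type libraries and 107 and 71.5 CPM in the libraries labelled abca7 +/-. The latter were near the background of 118 and 66.2 CPM in the pooled microglia-like and oligodendrocyte-like cells of the same libraries. Of the npy UMIs behind the 118 CPM, 1 microglia-like cell held 68 of 275 and 1 oligodendrocyte-like cell held 60 of 153. Without the richest cell of each class the background was 71.4 and 131 CPM in that PBS library. In the wild-type libraries microglia-like cells had npy at 111 and 186 CPM and oligodendrocyte-like cells at 107 and 329 CPM, so part of what remained is background.

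The neurotrophin gene bdnf was slightly lower after Ab42 in wild-type neurons, at 286 against 318 CPM (log2 ratio −0.15, interval −0.24 to −0.07). That direction was reversed at 2.44 with genes centred within each library and at 0.14 with the mean over cells, and the TMM interval of −0.16 to 0.01 included 0. The highest bdnf level was in glutamatergic-like neurons, at 413 and 489 CPM, where 240 of 843 and 126 of 420 cells had a bdnf UMI at 1000 UMIs per cell (64.2% and 67.1% without thinning). Only 1 and 2 shallower cells were left out, and the median depths were 5736.5 and 7144.5 UMIs. The background share in microglia-like cells was 3.47% and 0.362%. The gene ngfra encodes the p75 neurotrophin receptor and of the 4 compared classes had its highest level in radial glia-like cells. The level in this class was lower after Ab42, at 215 against 374 CPM (−0.80, interval −0.94 to −0.66). Over all kept cells ngfra went the other way, at 108 against 63.2 CPM (0.77), and radial glia-like cells held 1191 of its 6180 UMIs after Ab42 and 689 of 1144 after PBS. The value over all kept cells also carries clusters 6, 9, 19 and 21, which had cells in the Ab42 library and 0 in the PBS library. The share of radial glia-like cells with an ngfra UMI was 14.2% after Ab42 and 22.1% after PBS, with 32 and 59 cells left out and median depths of 3511.5 and 3114 UMIs. Without thinning these shares were 41.9% and 46.1%. The background share in oligodendrocyte-like cells was 1.61% after Ab42 and 0 of 76 cells after PBS. The BDNF receptor gene ntrk2a was at 222 and 266 CPM in radial glia-like cells, and ntrk2b was at 65.9 and 69.2 CPM in neurons. The 10 measured neurotrophin and receptor genes had a median log2 ratio of −0.11 in neurons, at the 25.2 percentile of random lists.

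Gene lists fixed before the data were examined were read as the median log2 ratio of their members within a class, placed among 10000 random lists of like expression. Members counted as higher or lower differed at least 1.5-fold. In wild-type radial glia-like cells, genes of the interferon response and antigen presentation were lower after Ab42, with a median of −0.66 (6 higher and 16 lower of 29, percentile 0). The median was −0.20 at Leiden resolution 0.5 and −0.34 with a pseudocount of 10 CPM. Among the members isg15, which encodes a ubiquitin-like antiviral protein, was at 38.9 against 147 CPM, and the immunoproteasome gene psmb8a at 4.87 against 19.01 CPM. Mitochondrially encoded genes were also lower in these cells (−0.52, percentile 0), as were neural stem cell and Notch genes (−0.25, 4 higher and 9 lower of 38, percentile 0.12). Cholesterol synthesis genes were about level at −0.04 (percentile 32.6), and lipid transport genes at 0.02 (percentile 63.0).

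In wild-type microglia-like cells, complement and lysosome genes were higher after Ab42 (median 0.29, 10 higher and 3 lower of 33, percentile 99.9). The progranulin gene grn1 was at 2815 against 205 CPM and grn2 at 546 against 24.8 CPM, with 1 cell holding 765 of 1882 UMIs of grn2, while apoeb, the zebrafish APOE orthologue, was lower at 10126 against 18759 CPM. Cytokine and chemokine genes had a median of 0.88 (11 higher and 3 lower of 19, percentile 99.98); their largest ratio, for cxcl18b at 4.33, came mostly from 1 cell with 263 of 342 UMIs. The median of all measured genes was 0.18 in this class, and 0.30 in the comparison of genotypes after PBS, so list medians of microglia-like cells are read against those values. The interferon list had a median of 0.11 (percentile 62.4), the unfolded protein response list −0.40 (percentile 0.02) and nuclear genes of oxidative phosphorylation 0.39 (percentile 100). In oligodendrocyte-like cells myelin genes were lower (−0.36, 0 higher and 3 lower of 17, percentile 1.69), as were heat shock genes (−0.35, percentile 1.52), with hsp70.1 at 939 against 3239 CPM. Presynaptic genes had a median of 1.01 in these cells, so a larger share of RNA from neurons was not separated from the lower values.

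In wild-type neurons, postsynaptic genes were lower after Ab42 (median −0.23, 0 higher and 8 lower of 46, percentile 0.1), with the NMDA receptor genes grin2db at −0.95 and grin2bb at −0.81. Presynaptic genes had a median of −0.08 (percentile 10.7) and GABA receptor and synthesis genes −0.01 (percentile 65.6). Other neuropeptide and secretory granule genes had a median of 0.19 (12 higher and 6 lower of 35, percentile 99.99), with sst1.2 at 6.40, galn at 4.77 and crhb at 3.91. In each of these 3 genes a single cell held a large part of the UMIs, 2794 of 4329 for sst1.2, 2100 of 4985 for galn and 1605 of 2430 for crhb. Immediate early genes had a median of 0.11 (percentile 98.3). The 6 measured genes of the NPY system had a median of 0.13 (percentile 83.2), orthologues of Alzheimer's disease genes −0.03 (percentile 56.4), and kynurenine, serotonin and IL4 signalling genes −0.11 (percentile 34.3). Ribosomal protein genes were at −0.05 (percentile 5.74). Haemoglobin genes were at 3.58, from 3 members whose RNA can reach any droplet from red blood cells.

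Several of the genes ranked highest in this comparison were found in every class. The neuropeptide gene kiss1 had 750 UMIs in neurons after Ab42 and 0 after PBS, which allows at most 0.514 CPM. It had 616 UMIs in radial glia-like cells and 151 in oligodendrocyte-like cells, again against 0, and its log2 ratio over the cells outside the neuron class was 8.97. As kiss1 also led the unnamed cluster 6, found in the Ab42 libraries only, its RNA in these classes cannot be told from RNA of that cluster. The uncharacterised gene si:dkey-117i10.1 ranked first or near it in all 4 classes, and avp (732 UMIs against 0) in neurons; both also differed outside the class, at 9.02 and 5.88 beside the neuron ratios. Microglia-like cells had 2473 UMIs of the coagulation factor gene f13a1a.1 and 732 of tcnbb after Ab42, against 0 of both, found in 3.12% and 8.88% of the cells. They had 0 UMIs of caspb, which encodes an inflammatory caspase, and of aste1a after Ab42, against 114 and 103. The gene gnrh3 was lower in neurons, at 3 UMIs against 3175, of which 1 cell of the PBS library held 2499. Of the 3155 UMIs of si:ch211-5k11.8 in radial glia-like cells after Ab42, against 1 after PBS, nearly all were in 1 cell. Of the 24 genes ranked in the 4 classes, 19 differed more than 2-fold in the same direction outside their class. A further ranking without such genes, added after these values were seen, had fgfbp3 higher in neurons at 132 against 23.5 CPM, a gene at 10276 and 11384 CPM in radial glia-like cells that was also higher in oligodendrocyte-like cells at 385 against 39.1 CPM. It had the enkephalin gene penka lower at 87.2 against 381 CPM, although a UMI of it was found in more neurons after Ab42, 13.3% against 10.0%, and its log2 ratio outside the class was 1.16. It had cox7a1 lower in radial glia-like cells at 1.26 against 95.6 CPM.

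The second comparison set Ab42 against PBS in the fish labelled abca7 +/-. In neurons npy was higher after Ab42, at 689 against 342 CPM (log2 ratio 1.01, interval 0.95 to 1.07). In GABAergic-like neurons it was at 1795 against 873 CPM, and in glutamatergic-like neurons at 43.1 against 41.6 CPM. The 3 richest cells held 64.6% of the npy UMIs of neurons after Ab42. Without the 3 richest cells of each library the levels were about equal, at 245 and 247 CPM, and they were lower after Ab42 without 5 cells of each, at 157 against 216 CPM, and without 10, at 88.7 against 166 CPM. The share of neurons with an npy UMI was lower after Ab42, at 8.92% against 11.7% (24.2% and 26.0% without thinning), against a background of 7.40% and 9.04% in microglia-like cells. Those shares were taken from 1334 and 2199 neurons with median depths of 4934 and 4214 UMIs, leaving out 37 and 147. The microglia-like cells had median depths of 3959 and 3802.5 UMIs, and 129 and 182 of them were left out. The gene pyya was higher after Ab42, at 675 against 280 CPM (1.27). Its log2 ratio was 1.44 in glutamatergic-like neurons, at 824 against 304 CPM, beside 1.65 in wild-type fish. In GABAergic-like neurons it was 0.82, beside −1.08 in wild-type fish. The wild-type ratio of 1.65 was not separated from background, as pyya was also higher there in the other compared classes. In the line labelled abca7 +/- its log2 ratios were −0.37 in oligodendrocyte-like, 0.06 in radial glia-like and 0.09 in microglia-like cells.

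In the same neurons bdnf was slightly lower after Ab42, at 335 against 365 CPM (log2 ratio −0.12, interval −0.20 to −0.05). Radial glia-like cells had ngfra at 151 and 135 CPM (0.16, interval −0.06 to 0.38). The interval lay above 0 at Leiden resolution 0.5 (0.27, 0.09 to 0.46) and with TMM factors (0.22, 0.01 to 0.44). Over all kept cells ngfra was higher after Ab42, at 111 against 27.5 CPM (1.97), and radial glia-like cells held 355 of its 4832 UMIs after Ab42 and 349 of 1006 after PBS. Clusters 6, 9 and 21 made up 13.7%, 6.57% and 2.99% of this Ab42 library and had 0 cells in the PBS library. That ratio therefore also carries a difference in the cells of each library. The share of radial glia-like cells with an ngfra UMI was 12.5% and 10.8% (27.1% and 23.2% without thinning), with 115 and 124 cells left out and median depths of 2876 and 2428 UMIs. The background share in oligodendrocyte-like cells was 4.14% and 0 of 188 cells. The gene ntrk2a was at 143 and 164 CPM in radial glia-like cells. The neurotrophin and receptor list had a median of −0.13 in neurons and −0.37 in radial glia-like cells.

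**Figure D2:**
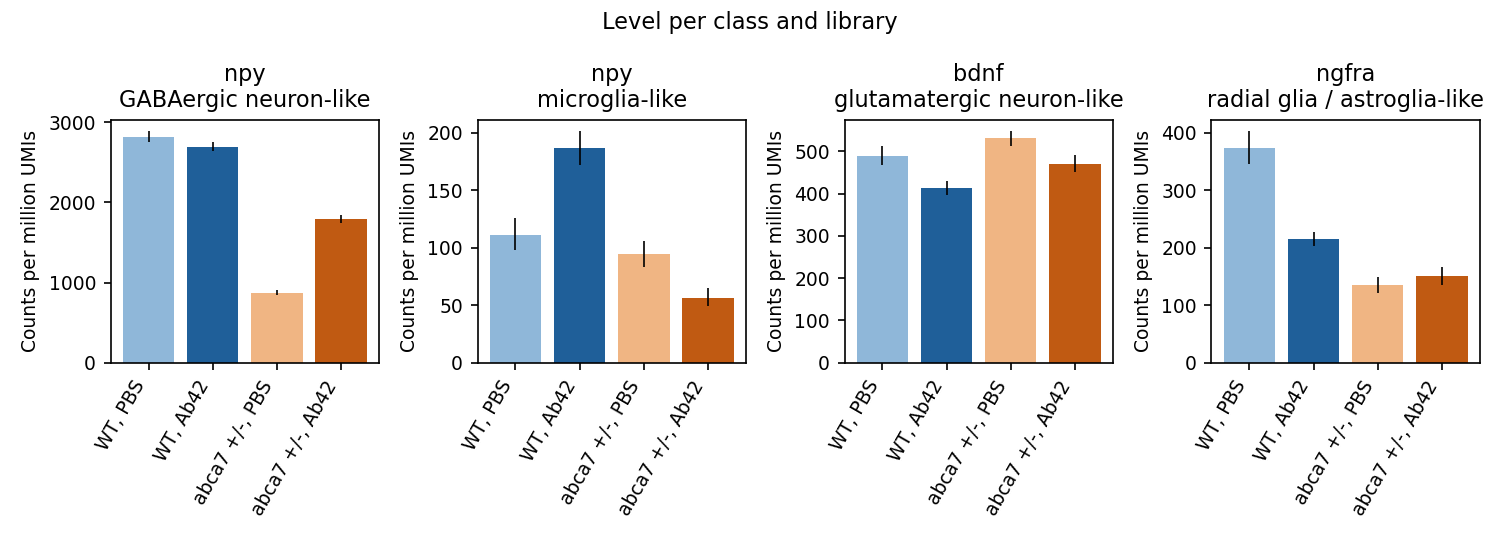
Bars give levels in CPM (y axis) in 4 panels, npy in GABAergic-like neurons and microglia-like cells, bdnf in glutamatergic-like neurons and ngfra in radial glia-like cells, for the 4 libraries (x axis), with exact Poisson 95% intervals as lines. In GABAergic-like neurons npy was at 2818 and 2694 CPM in the wild-type PBS and Ab42 libraries and at 873 and 1795 CPM in those labelled abca7 +/-, and ngfra in radial glia-like cells was at 374, 215, 135 and 151 CPM.

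Radial glia-like cells labelled abca7 +/- had higher levels of interferon response and antigen presentation genes after Ab42, with a median of 1.07 (20 higher and 1 lower of 29, percentile 100). The gene isg15 was at 197 against 15.8 CPM and psmb8a at 67.4 against 6.96 CPM, and UMIs of isg15 were found in 23.1% and 2.53% of the cells, against 3.14% and 1.19% of neurons and 44.2% and 23.8% of microglia-like cells, without thinning. Over all kept cells the list had a median of 0.72. Leaving out members that also differed outside the class gave a median of 0.41. Cholesterol synthesis genes were higher as well (1.05, 19 higher and 0 lower of 27, percentile 100), where the PBS library stood at −0.88 and the Ab42 library at 0.22 relative to wild type with the same injection. Among them were the sterol enzyme genes lss at 28.0 against 5.41 CPM, msmo1 at 639 against 185 CPM and hmgcs1 at 183 against 59.5 CPM. Neural stem cell and Notch genes had a median of −0.18 (2 higher and 7 lower of 38, percentile 0.22), and lipid transport genes −0.25 (percentile 2.02).

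In microglia-like cells labelled abca7 +/-, the interferon list was higher after Ab42 (median 1.15, 22 higher and 0 lower of 32, percentile 100), with mhc2dab at 2448 UMIs against 13 and the antiviral gene mxc at 1006 against 7. The level of mhc2dab also differed strongly between the PBS libraries of both lines, so its rise cannot be told from a difference between the fish used. Cell cycle genes were higher (0.65, 12 higher and 1 lower of 20, percentile 100), including dut at 1.63 and cdk1 at 1.38. Complement and lysosome genes had a median of 0.09 (11 higher and 4 lower of 33, percentile 94.8), reversed at −0.11 without members that also differed outside the class, with grn1 at 1580 against 158 CPM. Cytokine and chemokine genes had a median of 0.22 (percentile 98.8), and ccl19a.1 was at 4520 UMIs against 30. That gene is also among the leading genes of the macrophage or dendritic-like cells of cluster 24, which made up 1.39% of the kept cells after Ab42 and 0.562% after PBS. Heat shock genes were lower (−0.64, 1 higher and 10 lower of 19, percentile 0), as were lipid transport genes (−0.34, percentile 2.90), with the cholesterol exporter gene abca1a at 49.2 against 171 CPM and apoeb at 5019 against 14693 CPM. In neurons, postsynaptic genes had a median of −0.18 (0 higher and 0 lower of 46, percentile 0.04), immediate early genes −0.15 (percentile 0.27), and other neuropeptide genes 0.24 (13 higher and 3 lower of 34, percentile 100). Myelin genes were at −0.09 (percentile 15.3) and ribosomal protein genes at 0.45 (percentile 100) in oligodendrocyte-like cells.

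The genes ranked highest in this comparison were again led by kiss1 and si:dkey-117i10.1 in every class. Both, and ppp1r14ab below, were also leading genes of cluster 6, found in the Ab42 libraries only. In neurons kiss1 had 951 UMIs after Ab42 and 1 after PBS (log2 ratio 6.92 with 1 CPM added, counting interval 8.03 to 15.8), and the ratio outside the class was 10.66. The cohesin gene smc1a had 434 UMIs against 0 in neurons, and ppp1r14ab had 318 against 3 in radial glia-like cells. Oligodendrocyte-like cells had less slc7a10a, an amino acid transporter gene, at 9.70 against 109 CPM, and less mybphb, at 4 UMIs against 136. Of the 24 ranked genes, 21 differed more than 2-fold in the same direction outside their class. The ranking without such genes had sst1.2, a somatostatin gene, higher in neurons at 193 against 13.5 CPM, with 1 cell holding 888 of 1397 UMIs. It had timp2b higher in radial glia-like cells at 103 against 10.8 CPM, and ece1, an endothelin-converting enzyme gene, lower in microglia-like cells at 5.28 against 54.9 CPM.

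The third comparison set the fish labelled abca7 +/- against wild type after PBS. In neurons npy was lower in the library labelled abca7 +/- (log2 ratio −1.70, interval −1.76 to −1.64, −3.18 with genes centred within each library and −1.07 with the mean over cells). Among the GABAergic-like clusters it was lower in cluster 8, at 311 against 3035 CPM, but not in cluster 15, at 2403 against 2018 CPM. The NPY system list had a median of −0.62 in neurons (0 higher and 3 lower of 6, percentile 0.06). The level of ngfra in radial glia-like cells was lower (−1.46), and so was the cholesterol synthesis list (−0.88, 1 higher and 20 lower of 27, percentile 0), with lss at −2.46 and acat2 at −1.78. The interferon list was also lower there (−0.54, 3 higher and 12 lower of 26, percentile 0), with rsad2, which encodes the antiviral protein viperin, at 20.1 against 136 CPM. Immediate early genes were higher in neurons (0.35, 9 higher and 1 lower of 33, percentile 100) and in radial glia-like cells (0.55, percentile 100). Ribosomal protein genes were higher in radial glia-like cells (0.52, 27 higher and 2 lower of 90, percentile 100). Presynaptic and postsynaptic genes in neurons had medians of −0.20 and −0.25, both at percentile 0. In microglia-like cells mhc2b, a class II gene, had 384 UMIs against 3, and 1 gene known by a clone name had 616 against 0. The class II gene mhc2dab was lower, at 13 against 1007 UMIs, and caspb had 0 against 114. These opposite values of class II genes cannot be told from differences between the fish used. In oligodendrocyte-like cells rgcc was at 16.8 against 484 CPM and mybphb at 136 UMIs against 0, and heat shock genes had a median of −0.51 (2 higher and 8 lower of 19, percentile 0.01). Of the 24 ranked genes, 20 also differed more than 2-fold outside their class. The ranking without such genes had cart3 and cort, both neuropeptide genes, lower in neurons at 43.6 against 207 CPM and 51.4 against 207 CPM.

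The fourth comparison set the same groups against each other after Ab42. In neurons npy was lower in the library labelled abca7 +/- (log2 ratio −0.71, interval −0.76 to −0.66, and −0.56 with background subtracted). It was −1.88 with the richest 1% of neurons left out, at 71.5 against 266 CPM, levels that were partly background. Cluster 15 was lower, at 4872 against 12001 CPM. Cluster 8 was higher, at 1214 against 654 CPM, with 3 cells holding 94.2% of the npy UMIs of the library labelled abca7 +/-. The level of ngfra was lower in radial glia-like cells (−0.51). Interferon genes were higher in radial glia-like cells (median 1.22, 25 higher and 1 lower of 31, percentile 100), with psmb8a at 3.54 and gbp2 at 2.65, and in microglia-like cells (0.69, 19 higher and 0 lower of 32, percentile 100). Cell cycle genes were higher in microglia-like cells (1.18, 17 higher and 0 lower of 21, percentile 100), although the cycling gene top2a was found in 19 of 737 cells against 5 of 642. At 1000 UMIs per cell, a UMI of any cell cycle gene was found in 39.1% and 33.5% of microglia-like cells, against 21.7% and 20.9% of neurons. Cholesterol synthesis genes had a median of 0.22 in radial glia-like cells (percentile 99.8), and neural stem cell and Notch genes 0.21 (6 higher and 0 lower of 38, percentile 99.6). GABA receptor and synthesis genes in neurons were at −0.26 (percentile 0.01). Microglia-like cells had 323 UMIs of zgc:101699 against 0, 4 of tcnbb against 732 and 24 of f13a1a.1 against 2473. The gene cox7a1 in radial glia-like cells was at 46.2 against 1.26 CPM. Oligodendrocyte-like cells had hdac11, a histone deacetylase gene, at 165 against 44.1 CPM and ccn1 at 3 UMIs against 90. Of the 24 ranked genes, 19 also differed more than 2-fold outside their class. The ranking without such genes had the dynorphin gene pdyn higher in neurons at 138 against 53.7 CPM, and dnase1l4.1 higher in microglia-like cells at 131 against 1.16 CPM.

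**Figure D3:**
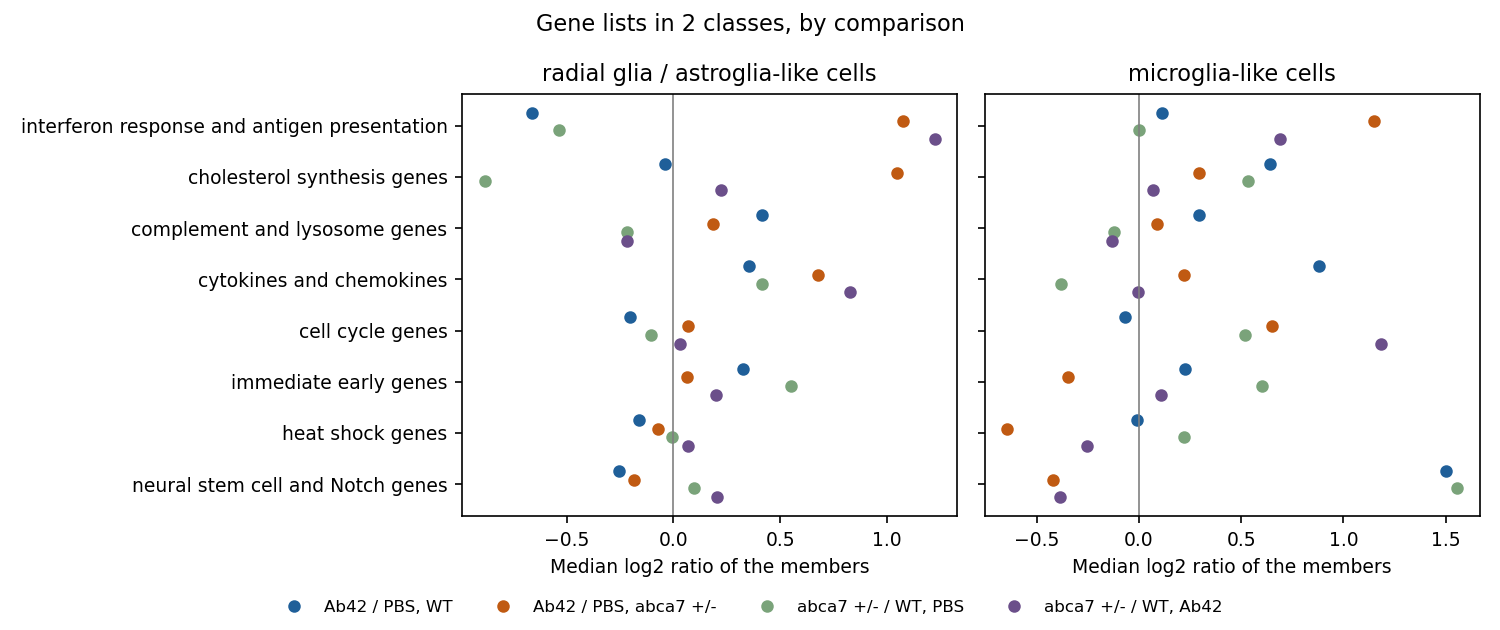
Each point is the median log2 ratio (x axis) of the measured members of a gene list (y axis) in radial glia-like or microglia-like cells, and colours mark the 4 comparisons. In radial glia-like cells the interferon list was at −0.66 for Ab42 over PBS in wild-type fish and at 1.07 in the fish labelled abca7 +/-, and the cholesterol synthesis list was at −0.04 and 1.05.

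The Ab42 ratios of both lines were then set against each other. For npy in neurons the log2 ratio of the line labelled abca7 +/- exceeded that of wild type by 0.98 (interval 0.91 to 1.06), but with the richest 1% of neurons left out both ratios were −0.57, at levels that were partly background. By part of the neurons the difference was 4.17 in cluster 8 and −1.55 in cluster 15. In cluster 8 of the Ab42 library labelled abca7 +/-, 3 cells held 94.2% of the npy UMIs, and without the 3 richest cells of each library the level there was 71.3 against 154 CPM, beside a background of 66.2 and 118 CPM. Over all kept cells the difference for npy was −0.49 (−0.55 to −0.43), from ratios of 0.48 in wild type and −0.01 in the line labelled abca7 +/-. That wild-type ratio also carries the unnamed clusters 0 and 2, which came almost wholly from the wild-type Ab42 library. Both clusters had npy among their leading genes, so the difference of −0.49 was not separated from a property of that library. For ngfra the difference between the lines was 0.96 in radial glia-like cells and 1.203 over all kept cells. Neurons carried the closest relation across genes, with Pearson r of 0.406 and Spearman rho of 0.319 between both Ab42 ratios over 11706 genes with at least 50 UMIs. In radial glia-like cells r was 0.271 and rho 0.135, in microglia-like cells 0.377 and 0.268, and in oligodendrocyte-like cells 0.223 and 0.108. Over the 10518 genes of neurons that differed less than 2-fold outside the class, r was 0.256 and rho 0.303. The same restriction gave 0.0972 and 0.111 in radial glia-like cells, 0.215 and 0.244 in microglia-like cells, and 0.0162 and 0.0909 in oligodendrocyte-like cells. The genotype ratios after PBS and after Ab42 gave r of 0.0849 and rho of 0.111 in neurons, 0.194 and 0.248 in radial glia-like cells, −0.0227 and −0.0907 in microglia-like cells, and −0.268 and −0.254 in oligodendrocyte-like cells. All of these correlations were taken across genes, which are not independent replicates.

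RNA of other cells was present in every class. Presynaptic genes, which microglia do not express, had a median log2 ratio of 1.05 in microglia-like cells for Ab42 over PBS in wild-type fish (29 higher and 0 lower of 40), and 1.1 for the line labelled abca7 +/- over wild type after PBS. In oligodendrocyte-like cells they had 1.01 and 1.21 in those comparisons, and −0.80 for Ab42 over PBS in the line labelled abca7 +/-. The ratio of a gene in a class that should lack it was therefore read as background.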

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

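Of the tests below, the share of foxg1a cells was laid down before its result was seen, and the tests of npy were chosen only after the npy values were seen.

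Clusters 6, 9 and 21 held cells outside the compared classes, found in the Ab42 libraries and with 0 cells in both PBS libraries, which allows at most 0.0761% and 0.0288% of those libraries by binomial upper bounds. In the wild-type Ab42 library and the Ab42 library labelled abca7 +/-, cluster 6 held 2.32% and 13.7% of the kept cells, cluster 9 held 3.91% and 6.57%, and cluster 21 held 1.40% and 2.99%. Kisspeptin (kiss1) marked cluster 6, at 5885 and 10192 CPM, and gng8 marked cluster 9, at 1664 and 3274 CPM, both habenula genes, a region named only after kiss1 had been seen. A state of telencephalic neurons after Ab42 was argued against by the telencephalic transcription factor gene foxg1a, found in 3.65% of 4496 cells of these clusters against 17.98% of 2908 neurons of the same libraries, a relative share of 20.3%. That share was within the range named in advance for tissue from outside the telencephalon, which may have been taken along in these dissections and would pass a sort by viability, while an effect of Ab42 on such cells stays open with 1 library per group.

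Cluster 19 likewise had 0 cells in both PBS libraries, and held 3.996% of the kept cells of the wild-type Ab42 library, 894 cells, and 0.102% of the Ab42 library labelled abca7 +/-, 14 cells. It was not named, its leading genes included afp4 and prph, and no explanation was tested for it.

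The higher npy level of neurons labelled abca7 +/- after Ab42, and the higher share of wild-type neurons with an npy UMI after Ab42, were weighed together. For that share, free RNA may account for the difference, since the share in classes that lack npy was 25.1% after Ab42 and 5.11% after PBS, a difference that is 197% of that in neurons. For the npy level, the ratio with background subtracted was 2.78 (2.58 to 3.02). Background was lower after Ab42, at 66.2 against 118 CPM, so subtraction could only raise the ratio and that test could not decide. Without the richest cell of each library, background was 51.2 against 71.4 CPM in microglia-like and 123 against 131 CPM in oligodendrocyte-like cells. A background that was not higher after Ab42 argues against free RNA, as measured in these classes, for the npy level. With GABAergic-like and glutamatergic-like neurons weighted equally the ratio was 2.01 (1.93 to 2.098). That ratio mostly repeated the npy levels of GABAergic-like neurons already given, 1795 against 873 CPM, so its outcome was known in advance. The share of GABAergic-like neurons was 47.0% after Ab42 and 49.3% after PBS, which argues against a higher share of them as the source. These values cover only this mix, so a different mix within the GABAergic-like neurons stays open. The intervals cover counting error only, and 3 cells held 64.6% of the npy UMIs of neurons after Ab42. A few cells with very many npy UMIs may carry the npy ratio of neurons, since it was 0.668 (0.601 to 0.742) without the richest 1% of neurons, at levels near background. An effect of Ab42 on those cells stays open.

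Some Ab42 ratios went in opposite directions in both lines, and this difference between the lines was not tested for any of them. In microglia-like cells the log2 ratio of npy was 0.74 (interval 0.53 to 0.96) in wild-type fish and −0.73 (−1.004 to −0.47) in the fish labelled abca7 +/-, and in oligodendrocyte-like cells 1.62 (1.07 to 2.23) and −0.69 (−1.13 to −0.28). In the wild-type PBS library 1 microglia-like cell held 161 of 251 npy UMIs, and without it the level was 39.9 CPM instead of 111 CPM. In the PBS library labelled abca7 +/- 1 microglia-like cell held 68 of 275 npy UMIs. Without the richest cell of each library the levels in that line were 71.4 CPM after PBS and 51.2 CPM after Ab42. In the PBS library labelled abca7 +/- 1 oligodendrocyte-like cell held 60 of 153 npy UMIs, and without it the level was 131 CPM against 132 CPM after Ab42, so the lower value there rested largely on 1 cell. These levels without 1 cell were added after the ratios were seen. The log2 ratio of bdnf was 2.02 (1.35 to 3.16) and −0.68 (−1.13 to −0.27) in microglia-like cells, and 1.41 (0.83 to 2.21) and −0.50 (−0.97 to −0.07) in radial glia-like cells. Free RNA of neurons was not excluded for npy and bdnf in these classes, since presynaptic genes had medians of 1.05 and −0.31 in microglia-like cells, 1.01 and −0.80 in oligodendrocyte-like cells, and 0.52 and −0.21 in radial glia-like cells, in the same directions. The cholesterol regulator gene insig1 was at 0.51 (0.18 to 0.85) and −0.28 (−0.51 to −0.05) in oligodendrocyte-like cells. In radial glia-like cells isg15 was at −1.89 (−2.18 to −1.65) and 3.55 (3.17 to 4.13), and psmb8a at −1.77 (−2.75 to −1.20) and 3.10 (2.57 to 4.07).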

How the results depend on the processing

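Of the alternatives, those on background npy, the npy-richest neurons, members differing outside the class, all kept cells and 10 npy UMIs were chosen after the data were seen. No paired analysis was possible because each group had 1 library. For 17 list medians, the direction held in all 17 under each alternative except TMM factors, at least 100 UMIs per member, and leaving out members differing outside the class, where it held in 16. For 108 gene ratios, under the alternatives run on all of them, it held in all except 1 under Leiden resolution 2, 2 under centring and 2 under the mean over cells. Of the 108, 96 were the ranked genes, chosen for their extreme ratios in these data, so their direction could hardly change. For the 4 npy ratios in neurons it held in 3 with background subtracted and in 2 without the richest 1% of neurons. The log2 ratios of npy in neurons are given in the order Ab42 over PBS in wild type, in the line labelled abca7 +/-, and that line over wild type after PBS and after Ab42. The first was 0.19 at resolution 0.5, −0.0245 at resolution 2, −1.36 with centring, 0.20 with doublets removed and 0.10 with TMM. The second was 0.91 at resolution 2, 1.21 with at least 500 genes and at most 5% mitochondrial UMIs, and 1.15 with all barcodes. The third was −1.62 at resolution 2, −3.18 with centring, −1.92 with the stricter filter, −1.82 with all barcodes, −1.63 with doublets removed and −1.63 with TMM. The fourth was −0.89 at resolution 0.5, −0.85 with centring and −0.86 with doublets removed. The mean over cells gave −0.13, 0.0944, −1.07 and −0.85, subtraction of background −0.12, 1.47, −2.15 and −0.56, and leaving out the richest 1% of neurons −0.57, −0.57, −1.88 and −1.88, so that the second was reversed. For bdnf in wild-type neurons the ratio was −0.60 at resolution 0.5, −0.28 with the stricter filter, −0.25 with all barcodes, and reversed at 2.44 with centring and at 0.14 with the mean over cells, which gave −0.0149 in the line labelled abca7 +/-. For ngfra in wild-type radial glia it was −1.05 at resolution 0.5. The interferon list in radial glia was at −0.20 in wild type at resolution 0.5, −0.76 with centring and −0.34 with a pseudocount of 10 CPM. In the line labelled abca7 +/- it was at 0.92 with that pseudocount and 0.41 without members differing outside the class. Cholesterol genes in the radial glia of that line were at 0.67 at resolution 0.5, 1.24 with doublets removed and 0.85 with that pseudocount. Complement and lysosome genes in its microglia were reversed at −0.11 without members differing outside the class. For each of these values the cause was not tested.

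Shares moved as well, and the cause was not tested. In library order, neuroblast-like cells made up 5.61%, 3.57%, 12.197% and 10.9% of named cells at resolution 2, and 1.76%, 0.492%, 5.37% and 3.48% of all kept cells. In the wild-type PBS library they made up 1.83% with all barcodes and 1.97% with doublets removed. In the wild-type Ab42 library they made up 1.14% at resolution 0.5 and 2.57% with centring. In the PBS library labelled abca7 +/- they made up 11.2% at resolution 0.5, 10.6% with centring and with the stricter filter, 8.52% with all barcodes and 8.48% with doublets removed, and in the Ab42 library 10.2% at resolution 0.5 and 9.38% with the stricter filter. Their share was higher in both libraries labelled abca7 +/- under each of these. The share of neurons with an npy UMI was 7.50%, 13.8%, 8.99% and 5.84% at 500 UMIs per cell, 23.3%, 60.04%, 26.0% and 24.2% without thinning, and 4.15%, 2.53%, 1.79% and 1.60% with at least 10 npy UMIs. Correlations in neurons were 0.443 for the Ab42 ratios and 0.124 for the genotype ratios over genes with at least 200 UMIs. Of the other values, 356 gene ratios moved and 644 did not, as did 18 and 135 list medians and 106 and 70 shares. Depth limited genes with few UMIs most, such as abca7 and npy1r.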

Other observations

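The tests of clusters 0 and 2 were chosen only after their size was seen, and the values in the next paragraphs were picked out after the data were seen.

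Progranulin genes were among the members furthest from equal in microglia-like cells of both lines after Ab42. The gene grn1 was at 2815 against 205 CPM in wild-type fish and at 1580 against 158 CPM in the fish labelled abca7 +/-. The glycoprotein gene gpnmb, expressed by lipid-laden phagocytes, had 139 UMIs against 0 in wild-type microglia-like cells. In the Ab42 library labelled abca7 +/- it had 21 UMIs, 17 of them in 1 cell. The class II gene mhc2dab had 1007 and 1475 UMIs in microglia-like cells of the wild-type PBS and Ab42 libraries, and 13 and 2448 in those labelled abca7 +/-.

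The peptide genes oxt, avp and kiss1 had higher levels in both Ab42 libraries. Over the kept cells outside clusters 6, 9 and 21, oxt, which encodes isotocin, was at 164 CPM in the wild-type Ab42 library and 32.4 CPM in the Ab42 library labelled abca7 +/-, and avp was at 63.9 and 17.0 CPM. In the PBS libraries oxt was at 0.552 and 0.328 CPM, and avp had 0 UMIs. The PBS libraries had kiss1 at 0 and 0.0821 CPM over the same cells, against 275 and 276 CPM in the Ab42 libraries. As kiss1 marked cluster 6, found in the Ab42 libraries only, its RNA in other cells cannot be told from RNA of that cluster. The oxt level of 164 CPM includes clusters 0 and 2, which came almost wholly from the wild-type Ab42 library. Both clusters had oxt among their leading genes. For oxt and avp, tissue from outside the telencephalon was not tested as a source, so an effect of Ab42 is not shown.

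Clusters 0 and 2 came almost wholly from the wild-type Ab42 library, cluster 0 with 8280 of its 8456 cells and cluster 2 with 3649 of its 4014. Cluster 0 had a median of 513 genes, and its leading genes included several peptide genes, oxt, npy, sst1.1, penkb, pyya and cckb. Also among them were gng8, which marked cluster 9, and the haemoglobin gene hbba1, an RNA that can reach any droplet from red blood cells. Leading genes of cluster 2 included oxt, npy, sst1.1 and mt-atp6. In clusters 0 and 2 the median level of microglia markers was 0.197 of that in the other kept cells of the library. It was 1.77 for neuron markers, 0.466 for radial glia markers and 0.803 for oligodendrocyte markers. The low microglia value would count against droplets filled with the pooled RNA of all classes, but the smallest barcode had 500 UMIs, so the make-up of free RNA was assumed and not measured, and the test leaves free RNA open. RNA mainly from damaged neurons may also fill these droplets, and a state of neurons after Ab42 in wild-type fish stays open, since it cannot be separated from a property of that 1 library.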
